A study of Mus musculus with 4 samples.

How the data were processed

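The series holds 4 arrays of mouse embryonic 3T3 fibroblasts, an immortal line that divides in serum. Per the labels' protocols, the cells were kept overnight in 0.5% serum and were then either harvested (basal) or given tumour necrosis factor (TNF), an inflammatory cytokine, for 0.5, 2 or 12 h. The TNF concentration was 10 ng/ml for 0.5 h and 12 h; the protocol text of the 2 h sample repeats that of the basal sample and names no concentration, and its title and source name put it at 2 h of TNF. Per the labels' protocols, 8 µg of total RNA was labelled and hybridised to Affymetrix 430 2.0 arrays, which cover the mouse genome with short oligonucleotide probes. Groups were taken from the sample labels, with 1 array in each of the 4 groups, so no spread between replicates exists and 0 tests were run.

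The deposited values are linear intensities, 1 per probe set and array, and all lie above 0. The signal algorithm and any scaling between arrays that the authors used are not given in the sources used here. Each array held 45101 probe sets, of which 64 were control probe sets. The probe annotation gave 1 gene for 34958 probe sets and several for 932, and 9160 were not listed there; a probe set of several genes or none named no gene. The symbols of 34754 probe sets were found in a table of RefSeq genes of the GRCm38.p6 assembly, which was used for names only, and 0 symbols changed. No genome build is named for the array values, so no coordinates are given.

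Signals under the 30th percentile of all values of the 4 arrays (9.09) were raised to that floor, and a ratio with 1 side at the floor is written as "at least". Each gene was represented by its probe set with the highest mean log2 signal. Of 18193 named genes, 1924 lay at the floor on all 4 arrays and 16269 were analysed. The log2 ratio of each TNF array to the basal array, and of each array to the one before it, was taken from the deposited values with no further scaling. A gene rose or fell if its ratio was at least 2-fold. An induced gene was put in a time class by the time of its highest signal among the 3 TNF arrays. These choices were made before the data were examined.

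A second floor at the 75th percentile of all values (signal 102), called the higher floor below, was chosen after seeing the data, because low signals scattered past 2-fold. With it, 7311 genes were analysed. To show how many genes scatter alone takes past 2-fold, sets of 4 unchanged arrays were drawn 100 times, each probe set at its mean log2 signal plus normally distributed noise. The noise at each of 40 signal levels was set from the median absolute deviation of a ratio to the basal array. The ratio at 0.5 h was used first and in the self-test; its scatter is narrower than at 2 and 12 h, so 100 further draws, added after seeing this, took the noise of all 4 arrays from the 12 h ratio. Real changes widen the noise, so a total that stays within draws set from its own ratio leaves open whether it exceeds scatter, and outlying probe sets beyond a normal distribution are not drawn. Overlaps between times were set against the same draws, which share the basal array, and against independent lists.

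Before the data were examined, 30 gene lists with 433 different genes were fixed. They were NF-kB feedback inhibitors, NF-kB subunits, immediate early transcription factors, MAP kinase phosphatases, mRNA decay and RNA-binding regulators, CXC and CX3C chemokines, CC chemokines, cytokines and growth factors, adhesion molecules, TNF receptor signalling, survival genes, interferon response, antigen presentation by MHC class I, complement and acute phase, and metalloproteinases. The others were prostaglandin synthesis, collagens and matrix, contractile and SRF or TGF-beta targets, G1/S, G2/M, cholesterol synthesis, oxidative stress and metallothionein, unfolded protein response, ribosomal proteins and reference genes, with markers of fibroblasts, adipocytes, macrophages and leukocytes, endothelium and epithelium. The array named no probe set for 43 of the 433 genes and 376 were analysed. Some genes stand in more than 1 list, such as Zc3h12a, B2m, Col1a1 and Dcn. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean signal in 20 levels; this percentile describes these arrays and is not a test.

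Named genes followed a fixed rule. For each time against basal these were the 10 largest increases and 5 largest decreases above the floor, the 5 highest genes that left the floor, and in each list with 3 or more members past 2-fold the 4 largest changes. The 8 genes with the largest ratio in each time class and 14 genes named in every comparison were added. Genes outside this rule are listed as such where they appear: other list members belong to the counts of their lists, and leading genes at the higher floor were chosen after their values were seen.

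The alternatives were floors at the 20th and 50th percentile and no floor, median centring, quantile normalization, loess on the mean level (span 0.4), the mean of a gene's probe sets, probe sets ending in _s_at, _x_at or _a_at left out, probe sets counted in place of genes, and rules of 1.5-fold and 3-fold. The calling step was tested on simulated data for the 0.5 h comparison. At the main floor, with 16142 genes in the step, it recovered 100% of 50 genes of high signal changed by 1.5 (log2), in each direction. The same held for 50 such genes changed by 2.5. With 7200 genes at the higher floor it recovered 100% of both sets of rises. There it recovered 80% of changes of -1.5 and 78% of changes of -2.5, since a fall stops at the floor. The rises had the same median log2 ratios at both floors, 1.485 and 2.502. This followed from the choice of genes, whose mean signal was already 102 or more. A rise that starts well under 102 is cut short by the higher floor, and such rises were not simulated. Recovery among genes of low signal, where scatter is wider, was therefore not tested, and the 100% at the main floor does not cover them. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9. The number of arrays limits the precision of every value.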

Results

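RNA levels of mouse 3T3 fibroblasts were measured on 4 oligonucleotide arrays, 1 of basal cells and 1 each after 0.5, 2 and 12 h of TNF. The series title places the work in the question of how mRNA stability shapes the order in which inflammatory genes are induced; the arrays measured RNA levels, and stability itself was not measured. The median signal was 22.1 in basal cells, 21.3 at 0.5 h, 20.7 at 2 h and 19.9 at 12 h. The median log2 ratio to basal over all probe sets was -0.05, -0.12 and -0.20 at the 3 times. Ratios of 3' to 5' signal, a check of RNA integrity, were 1.21, 1.24, 1.24 and 1.26 for Actb and 0.736, 0.756, 0.736 and 0.776 for Gapdh, while the 5' signal of 18S rRNA went from 462 to 382, 273 and 263. Over the 11207 probe sets with a signal above 102, Pearson's r between arrays on the log2 scale ran from 0.965 (basal and 12 h) to 0.987 (basal and 0.5 h), across probe sets, which are not replicates. With 1 array per group and no test, "rose", "fell" and "changed" mean at least 2-fold by the fixed rule. The scatter of the 0.5 h ratio depended on signal: its scaled median absolute deviation was 1.69 (log2) under a signal of 8, 0.59 between 16 and 32, 0.25 between 64 and 128 and 0.07 above 1024. The ratios at 2 and 12 h spread more widely, by 0.31 and 0.39 between 64 and 128 and by 0.10 and 0.19 above 1024.

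The first comparison asked which genes differed from basal after 0.5 h of TNF. The series has no array of cells kept in low serum for 0.5, 2 or 12 h without TNF. At each time, rises as well as falls may therefore combine effects of TNF and of the added time. The chemokine genes Ccl20, Cxcl1 and Ccl2 and the NF-kB inhibitor genes Tnfaip3 and Nfkbia were among those with large increases. Ccl20 (1422029_at), a chemokine for lymphocytes and dendritic cells, rose 46.8-fold from a signal of 12.5 to 584, and the neutrophil chemokine Cxcl1 (1419209_at) 21.2-fold from 151 to 3211. Ccl2 (1420380_at), which attracts monocytes, rose 9.63-fold to 1641. Tnfaip3 (1433699_at), encoding the NF-kB inhibitor A20, rose 9.42-fold from 268 to 2521, and Nfkbia (1420088_at), encoding IkB-alpha, 4.06-fold from 1843 to 7476. Cxcl10 rose 8.04-fold, Nfkbiz 6.35-fold, Ccl7 6.32-fold and Irf1, an interferon-response transcription factor, 6.30-fold. Cxcl2 (1449984_at) went from under the floor to 203, at least 22.3-fold higher.

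Of the 10 CXC and CX3C chemokines, 5 rose at 0.5 h, with a median log2 ratio of 1.22; Cxcl5 rose 3.72-fold, from 493 to 1834. Of 11 CC chemokines, 4 rose, the smallest being Ccl9 (2.03-fold, to 69.4), and the list's median was 0.59. Among 11 NF-kB feedback inhibitors 5 rose and 0 fell, including Nfkbie (2.37-fold) and the RNase gene Zc3h12a (3.47-fold, to 70.5). That name is the one given to the fixed list and need not describe every member, such as Bcl3 or Nfkbiz. The list of immediate early transcription factors holds 21 genes that growth factors and stress induce without new protein, and 4 of them rose. They were Ier3 (3.94-fold, to 4064), Fos (from 151 to 526, log2 ratio 1.81), Junb (2.13-fold) and Ier2 (2.06-fold). Ier3 does not itself encode a transcription factor, and the whole list is called immediate early factors below. Jun went from 432 to 803, a log2 ratio of 0.89, short of the rule, and Egr1 from 2174 to 3688 (0.76). Zfp36, encoding the mRNA-destabilising protein tristetraprolin, rose 5.77-fold from 95.6 to 552, and with Zc3h12a was 1 of 2 among 18 regulators of mRNA decay to rise; 0 of the 18 changed at 2 or 12 h. The cytokine gene Lif rose 6.18-fold to 222 on 1 of its 2 probe sets, the other giving -0.51; Tnf itself and Csf2 left the floor to reach 25.3 and 21.1 (at least 2.78-fold and 2.32-fold), so 3 of 19 cytokines and growth factors rose. Vcam1, an adhesion molecule for leukocytes, rose 2.29-fold from 269 to 618, while Icam1 was at 19.1 and 21.5. Relb rose 2.29-fold to 46.4, the only 1 of 4 NF-kB subunits to change.

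In the interferon response list of 27 genes, 3 rose and 1 fell at 0.5 h: beside Irf1, Ifi47 rose at least 4.05-fold to 36.8 and Iigp1 2.16-fold to 25.6, and Ifih1 fell 2.09-fold to 36.2. Ccl5 (13.6) and Il6 (10.2) lay close to the floor at this time, and Mmp3 had a log2 ratio of 0.22; 0 of 16 metalloproteinases and inhibitors and 0 of 13 genes of antigen presentation changed. Of 11 complement and acute phase genes Saa1 rose and Saa3 fell 2.57-fold to 11.3. Most of the other genes that the naming rule gave had low signals. Lce1h and Wdtc1 rose to 87.4 and 68.4. Fam131c, Golga7b, Il15ra and Mycn went from under the floor to between 41.1 and 44.3. Slc36a3, 4732491K20Rik, Gm7788 and Krtap26-1 fell by 2.27, 2.23, 2.21 and 2.20 (log2) from basal signals of at most 50.4. Kcnj11 fell by 2.14 from 143, but its other probe set was higher by 2.77, and the mean of its probe sets gave 0.32; for Mycn that mean gave -0.53.

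By the fixed rule 415 genes rose and 481 fell at 0.5 h, of 16269. Unchanged arrays drawn at the scatter of this same ratio gave a median of 502.5 higher and 506.5 lower; the likeness is built in, so these draws cannot show whether the totals exceed scatter. With the higher floor, chosen after seeing the data, 24 of 7311 genes rose and 1, Ces5a, fell, against at most 7 and 6 in arrays drawn at the wider scatter of the 12 h ratio, which are the drawn arrays from here on. Ces5a went from 204 to 69.8, and with the second signal raised to 102 it only just met the rule; with median centring, quantile normalization or loess 0 genes fell at this floor. Of the 24 genes, 8 had further probe sets that reached 102 on some array; these pointed the same way for 7 and all passed 2-fold for 6. The 5 probe sets of Nfkbia gave log2 ratios from 2.02 to 3.15, and the 3 of Cxcl1 from 3.27 to 4.79.

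**Figure D1:**
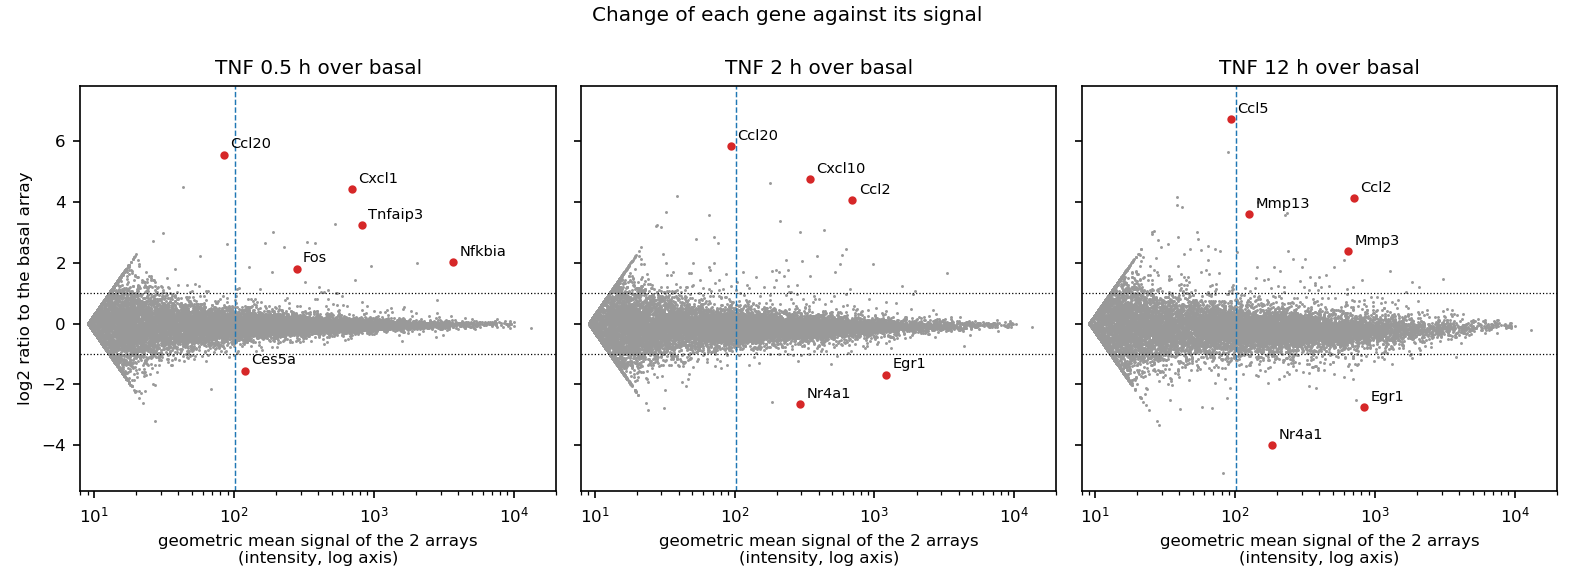
Log2 ratio of each gene to the basal array (vertical axis) against the geometric mean signal of the 2 arrays compared (horizontal log axis, intensity), with 1 panel each for 0.5, 2 and 12 h of TNF, 1 point per gene and some genes named in red. Dotted lines mark 2-fold and the blue dashed line a signal of 102; the points spread widely at low signal and narrow to the right, where Cxcl1 (4.41 at 0.5 h), Ccl2 (4.12 at 12 h) and Egr1 (-2.74 at 12 h) stand apart.

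At 2 h several chemokine genes stayed high, and genes of the adhesion molecule Icam1, the NF-kB subunit Nfkb2 and guanylate-binding proteins had joined them. Ccl20 stood 57.2-fold above basal (714), Cxcl10 (1418930_at) 26.7-fold (1777) and Ccl2 16.7-fold (2851). Nfkbie (1458299_s_at), encoding IkB-epsilon, rose 24.3-fold from 36.5 to 885. Icam1 (1424067_at), the ligand of leukocyte integrins, rose 11.9-fold from 19.1 to 228, and Ccl5 at least 18.2-fold to 165. Some genes of immediate early factors fell: Nr4a1 (1416505_at) fell 6.28-fold from 736 to 117, and Egr3 (1436329_at) 5.93-fold from 448 to 75.5, though its other probe set, of low signal, gave 0.04 (log2).

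Among chemokines at 2 h, 6 of the 10 CXC and CX3C genes rose (median log2 ratio 1.501), among them Cxcl1 8.45-fold, Cxcl5 3.88-fold, Cx3cl1 4.65-fold and Cxcl2 at least 4.64-fold to 42.2. Of 11 CC genes, 5 rose (median 0.73), with Ccl7 10.3-fold higher, and Ccl4 fell to a signal of 12.8. Of 11 feedback inhibitors 5 rose and 0 fell, with Tnfaip3 5.46-fold, Nfkbia 3.16-fold, Bcl3 3.04-fold and Nfkbiz 2.96-fold higher; the list's median was 0.98. Among 4 NF-kB subunits analysed, Relb rose 6.80-fold to 138 and Nfkb2 2.90-fold to 240.5. Of 12 adhesion molecules 3 rose: Icam1, Vcam1 (4.80-fold, to 1293) and Selp (2.24-fold, to 21.5). Fas, which encodes a death receptor, rose 3.37-fold and Ikbke rose to 32.8, which made 2 of the 16 genes of TNF receptor signalling. Birc3 (3.21-fold) and Birc2 (2.03-fold), which encode inhibitors of apoptosis, were the 2 of 9 survival genes to rise.

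The interferon response list had 8 of 27 members higher at 2 h and 0 lower, with a median log2 ratio of 0.46. Ifi47 rose at least 12.5-fold to 114, Gbp2 8.93-fold to 88.6, Irf1 4.12-fold to 621 and Gbp3 at least 3.94-fold to 35.8. Of 19 cytokines and growth factors 4 rose: Tnfsf11 4.64-fold to 44.6, Lif 3.40-fold to 122, Il15 3.14-fold to 86.5 and Csf2 at least 3.49-fold to 31.7. Mmp13, a collagenase gene, rose 3.97-fold to 143, while Mmp3 had a log2 ratio of 0.81. Tlr2, encoding a receptor for bacterial lipoproteins, rose 7.99-fold to 833 and Ch25h, encoding cholesterol 25-hydroxylase, 7.19-fold to 191. Casp4, Il15ra and Cmtm1 left the floor to reach 83.3, 86.4 and 51.4. Psmb10 (2.35-fold) was the only 1 of 13 antigen presentation genes and Ptx3 (2.10-fold) the only 1 of 11 complement and acute phase genes to rise. Il6 was under the floor.

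Of 21 immediate early factors 6 fell at 2 h and 1, Ier3 (2.36-fold), was higher. Beside Nr4a1 and Egr3, Egr2 fell 3.81-fold and Egr1 (1417065_at) 3.19-fold, from 2174 to 681; Klf4 fell by 1.07 and Klf2 by 1.01 on the log2 scale. Fos (-0.62), Jun (0.13) and Zfp36 (0.60) were short of 2-fold in either direction. Of 9 MAP kinase phosphatases, which switch off the kinases upstream of these factors, Dusp5 fell 3.17-fold to 26.4, Dusp6 2.10-fold and Dusp4 at least 2.35-fold, to under the floor. Nrxn3, Sirt4 and R3hcc1l, also given by the naming rule, fell from basal signals between 58.0 and 82.7. The 5 probe sets of Nrxn3 ranged from -2.78 to 1.30.

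By the fixed rule 420 genes rose and 586 fell at 2 h; unchanged arrays gave at most 677 and 692. With loess the split was 509 higher and 446 lower. With signals raised to the higher floor 35 rose and 12 fell, against at most 9 and 7 in the drawn arrays. The split was 43 and 6 with loess or quantile normalization and 42 and 6 with median centring, so with scaling the falls did not outnumber those of the drawn arrays. At that floor the genes that fell included Id2 (2.54-fold), the noncoding RNA Malat1 (2.35-fold), Rps27 (from 235 to 95.1) and Lmcd1 (2.05-fold). The 7 probe sets of Malat1 ranged from -1.23 to 0.43 on the log2 scale. For 5 of the 12, other probe sets reached 102 on some array; they pointed the same way for 4 and passed 2-fold throughout for 0. Probe sets of lower signal are not in this count, and for Egr3 and Ces5a these reached 0.04 and 1.37.

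At 12 h several chemokine genes were still high, the matrix-degrading enzyme genes Mmp3 and Mmp13 had risen, and most of the G2/M list had fallen. Ccl5 (1418126_at), a chemokine for T cells and monocytes, rose from under the floor to 957, at least 105-fold. Ccl20 stood above basal by 5.64 on the log2 scale, and Ccl2 17.4-fold (2961). Mmp13 (1417256_at) rose 12.1-fold from 36.0 to 437 and the stromelysin gene Mmp3 (1418945_at) 5.22-fold from 282 to 1471. Of 17 genes of the G2/M phase 16 fell, with a median log2 ratio of -1.36, against a median of -0.21 for random lists of the same size and signal.

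Of 11 CC chemokines 6 rose at 12 h and 0 fell (median log2 ratio 1.15), with Ccl7 at 825 (12.5-fold) and Ccl9 at 180 (5.26-fold). Of 10 CXC and CX3C genes 5 rose (median 0.86): Cxcl10 11.7-fold, Cxcl1 4.35-fold, Cxcl5 2.68-fold, Cx3cl1 2.65-fold and, at a signal of 48.2, Cxcl11. Cxcl2 was back at 10.6. Of 11 feedback inhibitors 4 rose, Nfkbie 15.8-fold, Tnip1 2.90-fold, Nfkbia 2.79-fold and Tnfaip3 2.12-fold, and Tnip2 fell 2.21-fold to 13.6. Nfkb2 (2.83-fold) and Relb (5.46-fold) were the 2 of 4 subunits that were higher. Icam1 (7.97-fold) and Vcam1 (3.61-fold) were the 2 of 12 adhesion molecules that were higher. Tnfsf11 (4.73-fold, to 45.4) and Il11 (at least 2.01-fold, to 18.3) rose and Il1b fell 2.55-fold to 12.6, while the other 16 cytokines did neither.

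The interferon response list had 12 of 27 members higher at 12 h and 0 lower, with a median log2 ratio of 0.95, against -0.15 for random lists. Gbp2 rose 14.8-fold to 147, Ifi47 at least 7.72-fold to 70.2, Oas1a at least 5.46-fold to 49.6, Usp18 4.53-fold to 41.8 and Bst2 2.72-fold to 266. Of the 12, only Bst2 and Ddx58 (to 207) rose at the higher floor. Of 13 genes of antigen presentation by MHC class I 6 rose (median 0.75): the immunoproteasome gene Psmb10 3.64-fold from 159 to 577, the class I gene H2-D1 3.04-fold to 782, Tapbp 2.60-fold to 2946, Psmb8 at least 2.60-fold to 23.6, H2-K1 2.27-fold and Erap1 2.24-fold. The 9 probe sets of H2-D1 ranged from -1.41 to 1.89, and class I genes are near-identical copies whose probes can cross-hybridise. Of 11 complement and acute phase genes 5 rose: Lcn2, a siderophore-binding protein gene, 14.2-fold from 11.1 to 158, Cfb at least 3.67-fold to 33.3, Saa3 2.57-fold to 74.8, C1s1 2.52-fold to 587 and Ptx3 2.30-fold to 3114. Of 16 metalloproteinases and inhibitors 3 rose, the other being Mmp10 (4.90-fold, to 95.3). Casp4, an inflammatory caspase gene, rose at least 17.7-fold to 160, Abca1 7.15-fold to 104, and Cep126 and Chil1 from under the floor to 75.1 and 72.3. Mt2, a metallothionein gene, rose 4.28-fold from 289 to 1239, and Cdsn, outside the naming rule and picked at the higher floor, 4.31-fold to 538.

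The fall of G2/M genes at 12 h covered kinases, motors and kinetochore proteins. Kif23 (1455990_at), a motor of cell division, fell 2.98-fold from 403 to 135, Kif11 2.87-fold, Aurka (1424511_at), a mitotic kinase, 2.86-fold from 725 to 254, and Cenpf 2.76-fold. Only Bub1b (-0.89) of the 17 was short of 2-fold. The higher floor left 14 of the 17 lower. Of 17 G1/S and replication genes only Ccna2, whose cyclin also acts in G2, fell (2.53-fold); the list's median was -0.56. Among genes outside the naming rule, picked at the higher floor, the condensin gene Smc4 fell 5.67-fold from 1737 to 306, Id2 4.30-fold, Shcbp1 4.11-fold, Slc6a6 3.54-fold and Dlgap5 3.53-fold.

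Of 21 immediate early factors 9 fell at 12 h (median -0.91) and 1, Fosb, rose from under the floor to 18.9. Egr3 fell 29.8-fold (by 2.37 on the log2 scale for its other probe set, without a floor) and Nr4a1 from 736 to 46.1, Egr1 6.68-fold from 2174 to 325, and Fos 6.68-fold from 151 to 22.6. Jun (-0.44), Zfp36 (-0.27) and Irf1 (0.92) were within 2-fold of basal, and Il6 was under the floor. Dusp5 fell at least 9.20-fold and Dusp4 at least 2.35-fold, to under the floor. Nwd1 and Nrk fell to 15.2 and 25.9 from 107 and 179.

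By the fixed rule 454 genes rose and 842 fell at 12 h, and unchanged arrays, their noise set from this same ratio, gave at most 682 and 681. The split depended on scaling: it was 619 and 579 with median centring, 643 and 555 with quantile normalization and 662 and 529 with loess. Once signals were raised to the higher floor 45 rose and 126 fell, against at most 8 and 7 in drawn arrays. The split there was 59 and 72 with median centring and 68 and 54 or 67 and 54 with quantile normalization or loess. It was 37 and 78 with the mean of a gene's probe sets and 18 and 15 under the 3-fold rule. Every G2/M gene was still below basal after loess (17 of 17, median -1.14), with 11 past 2-fold. Of the 126 genes, 51 had further probe sets that reached 102 on some array, which pointed the same way for 50 and all passed 2-fold for 15. For the 45 genes that rose these counts were 16, 14 and 8. With low signals counted, the 3 probe sets of Kif23 ranged from -1.58 to 0.73.

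**Figure D2:**
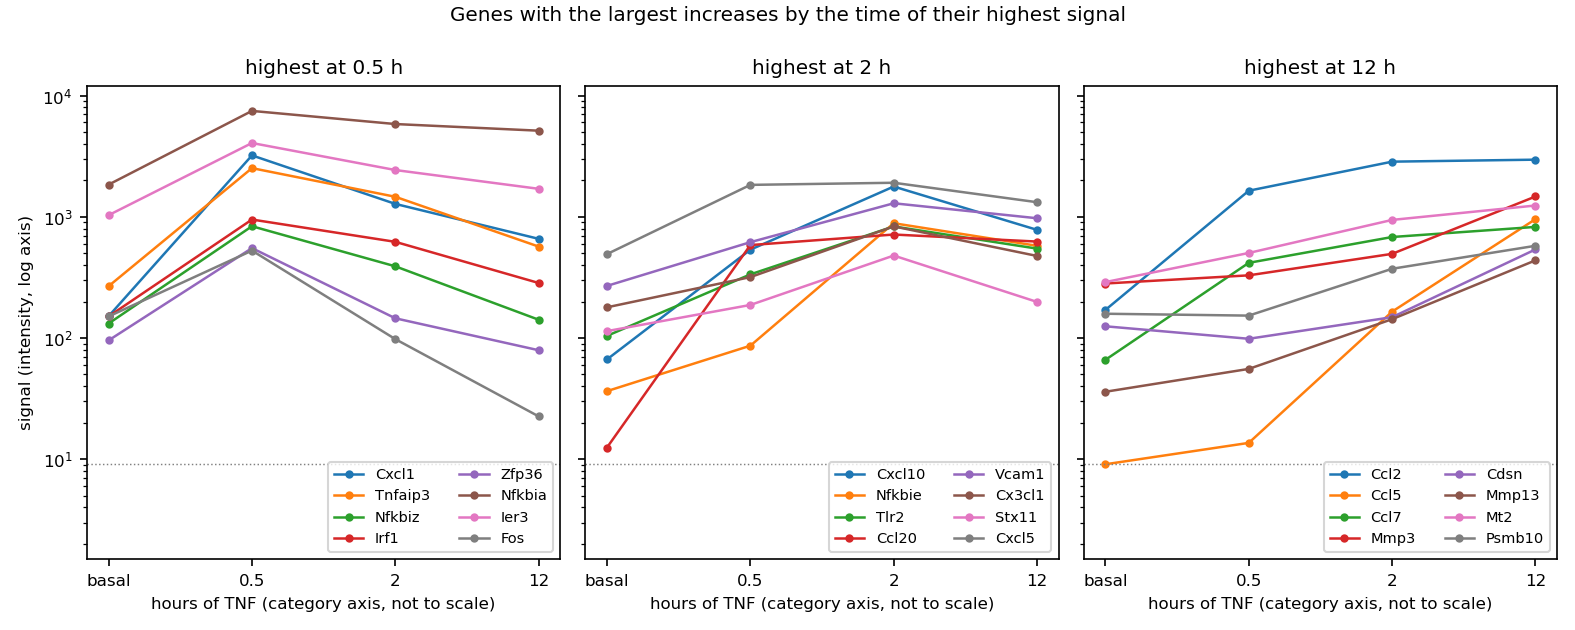
Signal (intensity, log axis) on the basal array and after 0.5, 2 and 12 h of TNF (category axis) of the 8 genes with the largest ratio in each time class at the higher floor, 1 line per gene and 1 array per point; signals under the main floor are drawn at it, on the dotted line. Cxcl1 was highest at 0.5 h (3211), Cxcl10 at 2 h (1777) and Mmp3 at 12 h (1471).

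Each induced gene was placed by the time of its highest signal, which gives the order of peaks and not that of first induction. Ccl20, highest at 2 h, had already risen 46.8-fold at 0.5 h. Ccl2 and Ccl7, highest at 12 h, had risen 9.63-fold and 6.32-fold by then. Cxcl1, Tnfaip3 and Nfkbia were highest at 0.5 h, Cxcl10, Icam1 and Vcam1 at 2 h, and Ccl5, Mmp3 and Psmb10 at 12 h. By this measure 15 genes peaked at 0.5 h, 23 at 2 h and 30 at 12 h at the higher floor, against at most 7, 9 and 8 in drawn arrays. The 12 h class moved with the method, to 50 with quantile normalization, 49 with loess and 19 without probe sets ending in _s_at, _x_at or _a_at. The 8 largest of the early class were Cxcl1, Tnfaip3, Nfkbiz, Irf1, Zfp36, Nfkbia, Ier3 and Fos. Those of the middle class were Cxcl10, Nfkbie, Tlr2, Ccl20, Vcam1, Cx3cl1, Stx11 and Cxcl5. Those of the late class were Ccl2, Ccl5, Ccl7, Mmp3, Cdsn, Mmp13, Mt2 and Psmb10. Neighbouring times differed little for some: Ccl20 had 714 at 2 h and 625 at 12 h, and Ccl2 2851 and 2961. At the main floor the classes held 323, 301 and 343 genes and drawn arrays gave medians of 521, 528 and 529. By list, 4 of 11 feedback inhibitors and 4 of 21 immediate early factors were in the early class at that floor. Of the adhesion molecules 3 of 12 peaked at 2 h, and 10 of 27 interferon response genes and 6 of 13 antigen presentation genes peaked at 12 h.

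From 0.5 to 2 h Cxcl1, Zfp36 and Fos declined while Nfkbie, Icam1 and Ccl5 increased. Over this step 19 genes rose and 22 fell at the higher floor (21 and 15 with loess or quantile normalization; at most 7 and 6 in drawn arrays), and by the fixed rule 423 rose and 481 fell, against at most 684 and 682 in drawn arrays. Cxcl1 went from 3211 to 1278, Zfp36 from 552 to 145 and Fos from 526 to 97.9. From 2 to 12 h, 10 genes rose and 35 fell at the higher floor (16 and 26 with loess, 16 and 24 with quantile normalization; at most 9 and 7 in drawn arrays), and 457 and 508 by the fixed rule, against at most 676 each. Over that step Ccl5 went from 165 to 957 and Mmp3 from 495 to 1471, while Cxcl10 went from 1777 to 780.

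Genes that rose at several times were shared beyond the drawn arrays. At the higher floor 14 genes rose at both 0.5 and 2 h, 12 at both 0.5 and 12 h, 21 at both 2 and 12 h and 11 at all 3 times, against at most 1 in any draw and at most 0.215 for independent lists. By the fixed rule the overlaps were 121, 125, 143 and 67. Drawn arrays that share the basal array gave at most 120, 123, 119 and 37, and independent lists 10.7, 11.6, 11.7 and 0.299. The comparisons share 1 basal array, so part of the excess may come from it.

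Few genes of the matrix, ribosomal, cholesterol and reference lists changed. Of 22 collagen and matrix genes, 19 were above the higher floor and 0 of those changed at any time; Col1a1 stayed between 3320 and 3455. At the main floor Lum rose at 0.5 and 12 h and Dcn fell at 0.5 and 2 h, both from signals under 20, and these are also the changes among 11 fibroblast markers. Of 12 ribosomal protein genes, 14 cholesterol genes and 11 reference genes 0 changed at any time, with medians at 12 h of -0.05, -0.32 and -0.23; the first turned to 0.11 with median centring. Ccn1 was the only 1 of 14 contractile and SRF or TGF-beta target genes to change, falling by 1.11 at 12 h. Mt2, higher at 2 h (3.26-fold) and 12 h, was the only 1 of 12 oxidative stress genes, and Trib3, higher at 12 h (2.41-fold), the only 1 of 12 unfolded protein response genes to change. Gadd45b rose at 0.5 h (2.72-fold) and Birc3 at 12 h (3.29-fold), the only 1 of 9 survival genes at each of those times. Traf1 and Map3k8 rose at 0.5 h to 19.3 and 43.6, and Fas (2.34-fold) and Ikbke (to 47.9) at 12 h, among 16 genes of TNF receptor signalling. Of 6 prostaglandin synthesis genes Ptges fell at 2 h to under the floor and Ptgs2, encoding cyclooxygenase, fell by 1.77 at 12 h, from 1116 to 328. Marker genes of other cell types gave low signals: 0 of 8 macrophage and leukocyte, 0 of 7 endothelial and 0 of 7 epithelial markers were above the higher floor. Among them at the main floor Spi1 rose at 0.5 h, Esam rose and Tek fell at 12 h, and Epcam (2 h) and Krt18 (2 and 12 h) fell. Of 5 adipocyte markers Fabp4 was at 1856 in basal cells with log2 ratios of 0.02, -0.18 and -0.36, and Cebpa fell at 0.5 and 12 h from 20.1.

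**Figure D3:**
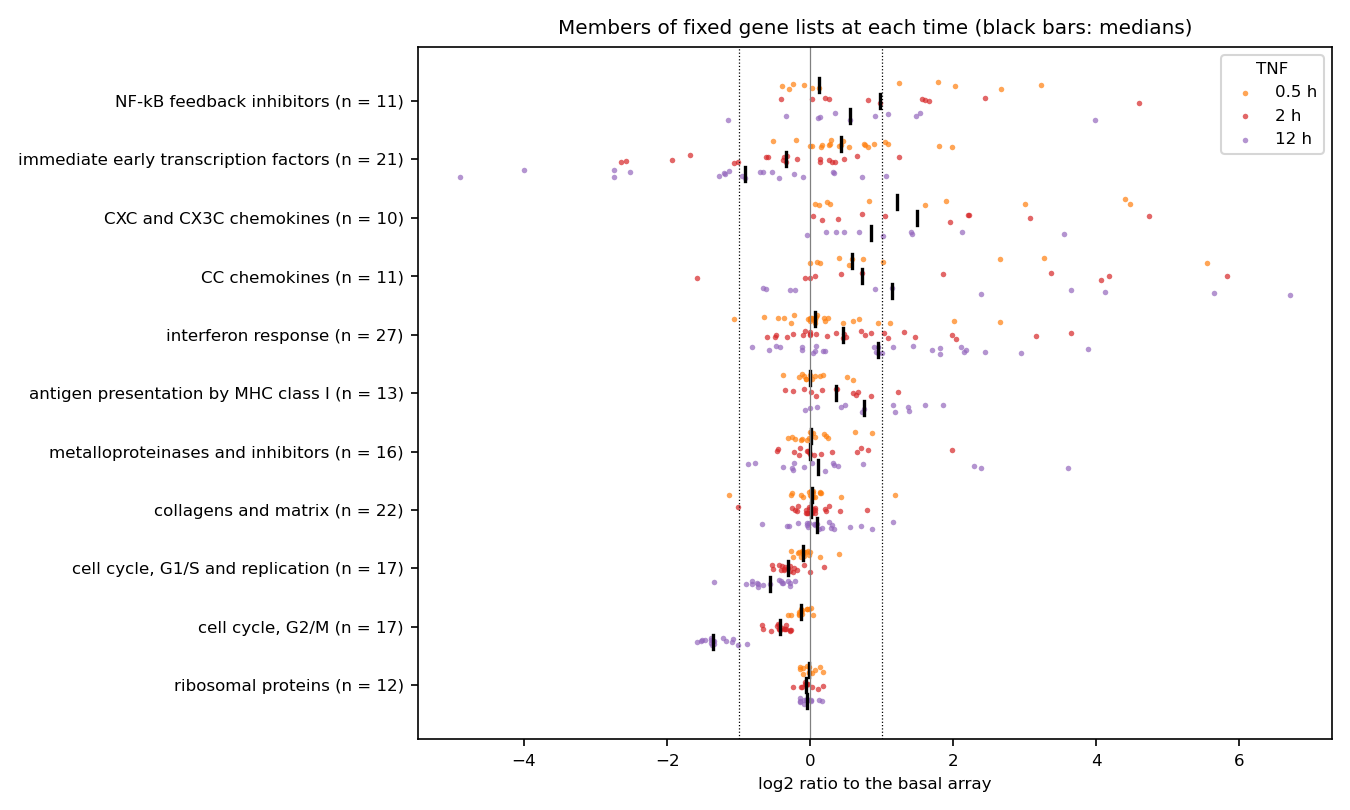
Log2 ratio to the basal array (horizontal axis) of each member of 11 of the fixed gene lists, 1 point per gene, at 0.5 h (orange), 2 h (red) and 12 h (purple) of TNF with 1 array per time; black bars are list medians and dotted lines mark 2-fold. Medians of CXC and CX3C chemokines were 1.22, 1.501 and 0.86, and those of G2/M genes -0.12, -0.42 and -1.36.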

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

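In this part the tests of an array-wide shift were chosen only after the result was seen. Of the genes that rose at 0.5 h with the higher floor, 4 fell at 12 h by the fixed rule at the main floor, opposite directions from the same basal array; the difference between the times was not tested, since each time has 1 array. At the main floor their log2 ratios at 0.5 and 12 h were 1.81 and -2.74 for Fos, 1.14 and -1.13 for Btg2, 1.04 and -1.13 for Ier2 and 1.002 and -1.32 for Klf10. After loess the 12 h values were -2.55, -0.93, -0.90 and -1.09, so Fos and Klf10 stayed past 2-fold and Btg2 and Ier2 did not. Klf10 sits at the 2-fold rule at 0.5 h.

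Immediate early factors as a list lay below basal at 12 h. At 2 h 6 of the 21 had already fallen, with a list median of -0.33, so the decrease began before 12 h. The ratios at both times rest on the same single basal array. A shift of the whole array at 12 h would leave a median near 0 after loess. It was -0.676 over the 21 genes, with 15 below basal and 6 past 2-fold, which argues against that shift as the whole cause. A longer stay in 0.5% serum may also lower these genes, and 0 arrays of cells kept 12 more hours in low serum without TNF are among the samples. The effect of TNF and that of time in low serum therefore cannot be told apart.

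Some probe sets that the annotation does not list, and that entered no comparison of genes, also changed. Of these 9160, 531 reached the higher floor on some array. With signals raised to it, 0, 4 and 6 were at least 2-fold higher than basal at 0.5, 2 and 12 h, against at most 1, 1 and 2 in unchanged arrays drawn at the scatter of the 12 h ratio. At the same times 0, 1 and 7 were lower, against at most 2 each, and with loess 4 were lower at 12 h. Probe set 1450173_at went from 120 to 552 at 2 h, and 1425145_at from 139 and 1422317_a_at from 178 to 702 and 881 at 12 h. Probe set 1423954_at went from under the main floor to 360 at 12 h, at least 39.6-fold.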

How the results depend on the processing

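Each group had 1 array, so no replicate could be left out, and depth here means signal over background: under a signal of 32 the scatter of 1 array against another passes 2-fold often. No paired analysis was possible because each group had 1 array. Of 121 named changes, all 121 kept their direction with median centring, quantile normalization and loess, and 119, 117 and 119 were still past 2-fold. A turn of direction was hardly possible there. All 121 were picked as at least 2-fold, while the arrays' median log2 ratios to basal were only -0.05, -0.12 and -0.20. With the floor at the 20th percentile or none all 121 were past 2-fold. This was fixed in advance, since a lower floor can only widen a ratio or leave it unchanged. At the 50th percentile 105 of 120 were past 2-fold, and at the 75th 58 of 81 that could be computed. Of those 81, 73 kept their direction. With the mean of a gene's probe sets 109 of 119 were past 2-fold and with _s_at, _x_at and _a_at probe sets left out 105 of 107. The mean of a gene's probe sets reversed Kcnj11 at 0.5 h, to 0.315, and Mycn at 0.5 h, to -0.533; their probe sets differ in sign. Of the 90 list medians (30 lists at 3 times), 42 lay outside the central 95% of random lists, and between 31 and 43 under the alternatives. The planned count of AU-rich elements by time class, with its alternatives, was not run, because transcript sequences were not used here. Counts from the fixed rule depend on the floor because low signals scatter past 2-fold; the cause of the other differences was not tested.

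With the floor at the 20th percentile, 1007 and 1090 genes were higher and lower at 0.5 h, 968 and 1260 at 2 h and 957 and 1552 at 12 h. From 0.5 to 2 h the counts were 985 and 1191 and from 2 to 12 h 1064 and 1117, and the time classes held 719, 635 and 639 genes. With no floor, 1643 and 1754 genes were higher and lower at 0.5 h, 1604 and 1999 at 2 h and 1622 and 2338 at 12 h. Between successive times they were 1627 and 1951 (0.5 to 2 h) and 1788 and 1879 (2 to 12 h), and the time classes held 992, 893 and 906 genes. At the 50th percentile 60 and 50 genes were higher and lower at 0.5 h, 100 and 95 at 2 h and 121 and 304 at 12 h. The steps then gave 86 and 84 from 0.5 to 2 h and 79 and 126 from 2 to 12 h, and the time classes held 46, 74 and 93 genes. At the 75th percentile, added after seeing the data, 24 and 1 genes were higher and lower at 0.5 h, 35 and 12 at 2 h and 45 and 126 at 12 h. From 0.5 to 2 h the counts were 19 and 22 and from 2 to 12 h 10 and 35, and the time classes held 15, 23 and 30 genes. Probe sets counted instead of genes, here and at the higher floor, took in those that the annotation does not list. By that count 1113 and 1320 were higher and lower at 0.5 h, 1073 and 1547 at 2 h and 1053 and 2200 at 12 h. Between successive times they were 1064 and 1283 (0.5 to 2 h) and 1049 and 1426 (2 to 12 h), and the time classes held 860, 773 and 789. Under a 1.5-fold rule 1230 and 1455 genes were higher and lower at 0.5 h, 1111 and 1815 at 2 h and 1236 and 2639 at 12 h. The steps then gave 1183 and 1619 from 0.5 to 2 h and 1390 and 1677 from 2 to 12 h, and the time classes held 858, 743 and 879 genes. Under a 3-fold rule 80 and 89 genes were higher and lower at 0.5 h, 89 and 91 at 2 h and 103 and 157 at 12 h. From 0.5 to 2 h the counts were 59 and 85 and from 2 to 12 h 71 and 68, and the time classes held 62, 62 and 83 genes. The genes higher at both 0.5 and 2 h, 0.5 and 12 h, and 2 and 12 h numbered 24, 19 and 35 under the 3-fold rule and 14, 12 and 21 at the 75th percentile. Genes lower at 12 h numbered 529 with loess and 555 with quantile normalization.

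With the higher floor, the 1.5-fold rule gave this: 49 and 18 genes were higher and lower at 0.5 h, 77 and 141 at 2 h and 129 and 698 at 12 h. Between successive times they were 69 and 129 (0.5 to 2 h) and 72 and 270 (2 to 12 h), and the time classes held 36, 48 and 102 genes. With the 3-fold rule there, 14 and 0 genes were higher and lower at 0.5 h, 20 and 3 at 2 h and 18 and 15 at 12 h. The steps then gave 4 and 5 from 0.5 to 2 h and 4 and 1 from 2 to 12 h, and the time classes held 8, 12 and 12 genes. With loess it gave 0 genes lower at 0.5 h, 6 genes lower at 2 h, 54 genes lower at 12 h, 16 genes higher at 12 h than at 2 h and 49 induced genes highest at 12 h. Under quantile normalization it gave 0 genes lower at 0.5 h, 6 genes lower at 2 h, 68 genes higher at 12 h, 54 genes lower at 12 h, 16 genes higher at 12 h than at 2 h and 50 induced genes highest at 12 h. With median centring it gave 0 genes lower at 0.5 h, 6 genes lower at 2 h and 72 genes lower at 12 h. Under the mean of a gene's probe sets it gave 4 genes lower at 0.5 h and 78 genes lower at 12 h. With _s_at, _x_at and _a_at probe sets left out it gave 0 genes lower at 0.5 h, 6 genes lower at 2 h and 19 induced genes highest at 12 h. Under probe sets in place of genes it gave 3 probe sets lower at 0.5 h, 197 probe sets lower at 12 h, 34 probe sets lower at 2 h than at 0.5 h, 18 probe sets higher at 12 h than at 2 h and 26 induced probe sets highest at 0.5 h.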

Other observations

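In this part the test of a dimmer array and that of an array-wide shift were chosen only after the results were seen. Several genes that stand in no fixed list changed at the higher floor, and were picked out after their values were seen; folds are given at the main floor. Edn1, encoding the vasoconstrictor endothelin-1, rose 3.64-fold at 0.5 h and was back at 68.2 by 2 h, against 66.8 in basal cells. At 2 h the transcription factor gene Cebpd rose 3.87-fold to 1114, Tnfaip2 3.40-fold, the sphingosine 1-phosphate receptor gene S1pr3 3.29-fold and Hk2, encoding a hexokinase, 2.42-fold. At 12 h Slc2a6, encoding a sugar transporter, was 5.07-fold higher, Cth, which makes cysteine, 3.60-fold, the antiviral Ifitm3 3.32-fold and Irak1 2.31-fold. In all, 6 of the 24 genes that rose at 0.5 h, 12 of the 35 at 2 h and 17 of the 45 at 12 h stood in no list.

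Of the 126 genes that fell at 12 h at the higher floor, 102 stood in no list; those named here were chosen after their values were seen. Nusap1 went from 752 to 300, Spc25 from 593 to 220, Kif20a from 583 to 218, Hmmr from 531 to 176 and Aspm from 205 to 78.9. Id1 and Id3, inhibitors of differentiation factors, went from 910 to 287 and from 1647 to 768.

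The fall between 0.5 and 2 h sets an upper limit on the half-life of an mRNA, if signal is proportional to mRNA and the 2 arrays are on 1 scale. Of the 24 genes that rose at 0.5 h at the higher floor, 8 fell at least 2-fold in those 1.5 h. With no new synthesis at all, the half-life would be 37.1 min for Fos, 46.8 min for Zfp36, 49.0 min for Edn1, 65.5 min for Ier2, 67.7 min for Cxcl1, 81.9 min for Nfkbiz, 85.8 min for Btg2 and 88.2 min for Klf10. With ongoing synthesis the true values would be shorter. Each value rests on the 1 probe set that represents the gene. For Nfkbiz no probe set was above a log2 ratio of 2.67 at 0.5 h, and another of its 3 stood at 1.99 at 2 h. That probe set thus fell less than 2-fold. Btg2 and Klf10 fell by 1.05 and 1.02 on the log2 scale, only just past the rule. No stability was measured on these arrays.

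The 12 h array was lower across most probe sets, with a median log2 ratio of -0.20. A dimmer hybridization or scan may explain it. The 18 spiked hybridization controls had a median log2 ratio of -0.09, and lay above genes of like signal by a median of 0.1 (SD 0.085, 15 of 18 above 0). The gap was larger than the 0.05 set for a dimmer array as the whole cause and, before rounding, just short of the 0.1 set for excluding it. Both bounds were written after the fall was seen, and the 18 probe sets measure only 4 spiked transcripts, so they are not independent. The controls themselves fell, which leaves a dimmer array open for part or all of the decrease.

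Genes of the G2/M phase fell at 12 h as a group, and the shift of the array does not account for it as a whole: after loess their median was -1.14. One hypothesis is that TNF slowed division, and another that the cells left the cycle during 12 more hours in low serum, which may lower the same genes. The series has 0 arrays of cells kept as long in low serum without TNF, so these cannot be told apart.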
